A study of Mus musculus with 16 samples.

How the data were processed

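Polyadenylated RNA of brain cortex was sequenced from 16 mice aged 9 months, in 4 groups of 4 (2 females and 2 males each): wild-type C57BL/6J, Dp16, 5xFAD and 5xFAD-Dp16. Per the labels' protocols, total RNA was extracted with TRIzol, poly-A enriched and made into strand-specific libraries with the Tecan/Nugen Universal Plus mRNA kit, and sequenced as paired ends on an Illumina NovaSeq instrument. The submitters' processing notes name bcl2fastq, FastQC 0.11.5, HISAT2 2.1.0, SAMtools 1.5, HTSeq 0.6.1 and the genome build GRCm38, without settings. The annotation, named in the title of the deposited tables, was GENCODE M24. Whether the counting used strand is not given in the sources used here, so values of overlapping and antisense genes are uncertain, as are those of gene families with near-identical copies such as the H2 and C4 genes.

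The authors deposited 2 tables of 55385 genes by 16 libraries. The first holds raw read counts per gene, which are deposited without normalization. The second holds RPKM values, which the authors scaled by gene length and library total. Dividing the counts by RPKM and by the library total gave a gene length that deviated from a whole number by at most 7.9e-10, so the deposited RPKM values are the deposited counts rescaled. Columns were matched to samples by title, and groups, sexes and replicate numbers were taken from the labels. Gene coordinates were taken from GENCODE M21, also on GRCm38, by gene identifier without its version; 241 genes had no match, 10 of them among the genes tested.

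Total counts ran from 16874481 to 22912168 per library. Xist counts were 1316 to 4588 in the libraries labelled female and at most 2 in those labelled male. Ddx3y counts were 870 to 1163 in males and at most 6 in females, so the sex label matched in 16 of 16 libraries. Replicate pairs within a group differed by far more than sampling noise, with a chi-square per degree of freedom of 17.2 to 302, so no library was counted as a copy of another. The labels name separate samples; nothing further in them describes litters or cohorts.

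The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM normalization, the filterByExpr low-count filter with its minimum count of 10, robust dispersion estimates over all 16 libraries, and sex as a covariate. It tested 17555 genes. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05. Errors of log2 fold changes are standard errors derived from the quasi-likelihood F statistic, and levels are given as TMM-normalized CPM with the SD over 4 libraries. The 5 pairwise comparisons, the interaction of both genotypes, and the difference of each genotype's effect between females and males were fixed before the data were examined, as were 37 gene lists with 782 symbols (779 found by name and 3 by synonym) and the triplicated segment as a further list. The lists cover microglial states, other immune cells, glia, vessels, neuron types, neighbouring brain regions, synapses, organelles and stress responses.

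Each list was tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The triplicated segment was taken as chromosome 16 from Lipi to Zbtb21 (75540514 to 97962622). Named genes followed a rule also fixed beforehand: App and Thy1 in each pairwise comparison; up to 8 higher and 8 lower called genes of largest fold change with a mean log2 CPM of at least 1, an approved symbol and no overlap between the groups' values, inside and outside the segment for the Dp16 comparisons; the 4 members of smallest p in each list past the threshold and up to 2 in other lists; and the 6 genes of smallest p in the interaction and sex contrasts. Outside this rule, nonagouti, Hprt, Trem2, Apoe, Ttr and Gm42418 were chosen after their values were seen. Genes named from the length-adjusted fit follow the same rule applied to that fit, which was itself added after the data were seen. Some genes that the rule selects are not reported.

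Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, no sex term, the replicate number as a block, fits of only the 2 groups compared, each library left out in turn, and limma-trend on log2(RPKM + 0.1) and log2(RPKM + 1). After the data were seen, 3 more were added: a covariate for the slope of expression on gene length per library, a fit without the 3 libraries of lowest slope, and limma voom with sample quality weights. The slope was the regression coefficient of a library's log2 CPM deviation on log2 gene length over protein-coding genes with a mean log2 CPM above 2.

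On simulated counts drawn from the real means and library sizes with 200 changed genes, the edgeR test recovered 3% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 97% of those changed 4-fold for Dp16 against wild-type (17256 genes tested). For 5xFAD against wild-type the shares were 3%, 43.3% and 93.9% (17289 genes), and for the interaction 1.5%, 16.4% and 77.3% (17253 genes). False calls made up 3.1% to 7.1% of the edgeR calls over the 6 simulated contrasts. In the simulated 5xFAD comparison DESeq2 made 23% false calls and limma-trend 6.1%. Each contrast was simulated once, with genes drawn independently and so without variation shared across genes. An arbitrary split of the real libraries, given below, called 7387 genes, so these shares may not hold for the real libraries.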

Results

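Cortical gene expression was measured at 9 months in wild-type mice, in Dp16 mice, in 5xFAD mice and in mice carrying both genotypes (n = 4 per group). Dp16 mice carry an extra copy of the distal part of mouse chromosome 16 that corresponds to much of human chromosome 21, and serve as a model of trisomy 21. 5xFAD mice express transgenes with familial Alzheimer's disease mutations, human APP among them, under the Thy1 promoter and form amyloid plaques. The groups allow the effect of the duplication to be read without and with the amyloid transgenes, and the effect of the transgenes without and with the duplication. Library totals were 16874481 to 22912168 counts, and 17555 genes were tested.

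Thy1, whose promoter drives the transgenes, checked the 5xFAD labels. Its level was 810 ± 62.8 CPM in wild-type, 888 ± 120 in Dp16, 1700 ± 199 in 5xFAD and 2000 ± 168 in 5xFAD-Dp16 (SD, n = 4 each), with no overlap between libraries with and without the transgenes. Mouse App, which lies in the triplicated segment (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766), stood at 1320 ± 413, 1870 ± 454, 1140 ± 172 and 1980 ± 277 CPM in the same order. Reads of the human transgenes were not counted apart.

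**Figure D1:**
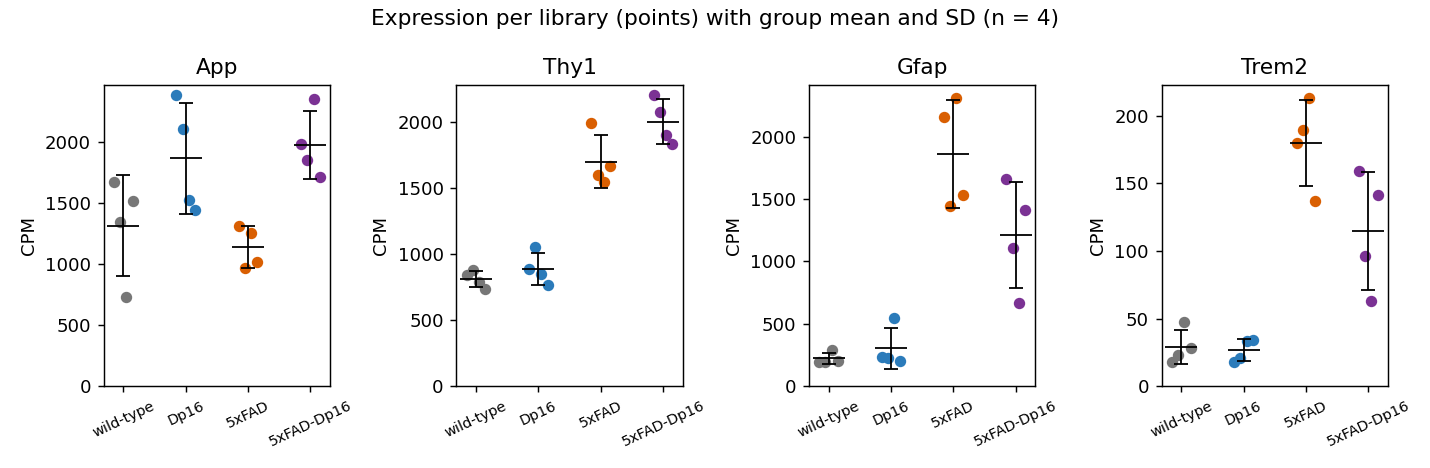
Expression in CPM (y axis) of App, Thy1, Gfap and Trem2 by genotype (x axis); points are libraries, lines the group mean and bars the SD (n = 4). Thy1 separated the 8 libraries with the amyloid transgenes from the others, and Gfap rose from a mean of 222 CPM in wild-type to 1860 in 5xFAD.

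The libraries also differed in how expression depended on gene length. The principal component with the largest share of variance (32.1%) correlated with the per-library length slope across the 16 libraries (Pearson r = 0.974, Spearman rho = 0.953). The permutation p = 1e-05 for each was the smallest that 100000 resamples can give. Without the 2 libraries farthest from the median slope r was 0.955. Both measures come from the same expression values, so the permutation does not show that gene length is what sets the libraries apart. Wild-type replicate 3 had the lowest slope (−0.439), followed by Dp16 replicate 4 (−0.181) and Dp16 replicate 3 (−0.171). Group means overlapped widely, at 0 ± 0.314 in wild-type, −0.057 ± 0.151 in Dp16, 0.021 ± 0.14 in 5xFAD and 0.036 ± 0.114 in 5xFAD-Dp16 (SD, n = 4). With the slope as a covariate, an alternative chosen after the data were seen, the common biological coefficient of variation fell from 0.292 to 0.161. The slope was taken from the same counts, so this fall does not show what lies behind it.

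**Figure D2:**
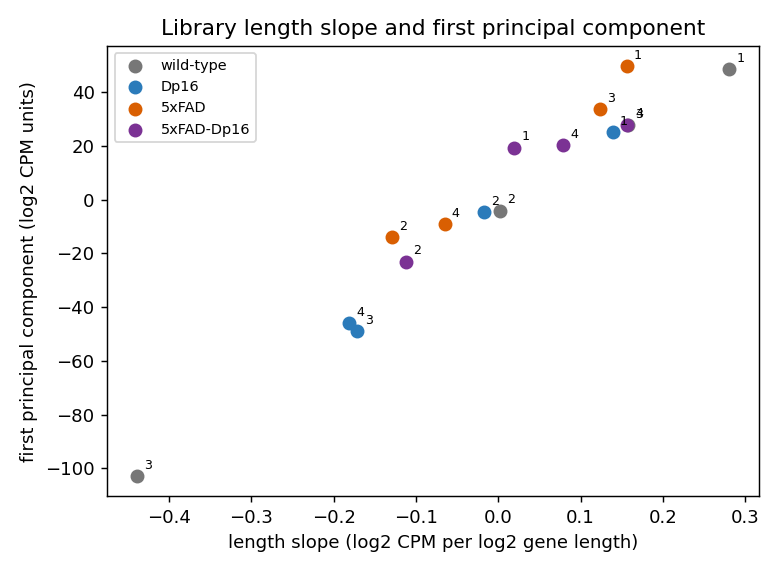
Score on the principal component of largest variance (y axis) against the slope of expression on log2 gene length (x axis) for the 16 libraries, coloured by genotype. The relation had r = 0.974 and wild-type replicate 3 lay at the low end with a slope of −0.439.

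Genes of the triplicated segment were higher as a group in Dp16 than in wild-type cortex, close to the ratio of gene copies. Of 109 segment genes tested, 98 had a log2 fold change above 0, and their median was 0.55 (interquartile range 0.36 to 0.66), or 1.46-fold. The 425 genes of chromosome 16 outside the segment had a median of −0.03. Per library, the segment median relative to the wild-type mean was 0.51 to 0.65 in all 8 libraries carrying Dp16 and −0.03 to 0.15 in the other 8. Examples were Jam2, a junctional adhesion molecule (0.81 ± 0.13, edgeR adjusted p = 0.158), Dnajc28 (0.81 ± 0.15, adjusted p = 0.303), Tmem50b (0.58 ± 0.13, adjusted p = 0.797) and App (0.51 ± 0.24, adjusted p = 1; log2 fold change ± SE, n = 4 per group).

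The segment passed the camera list test (adjusted p = 4.65e-66; adjusted p = 1.73e-09 with an estimated correlation). So did the 4 interferon and interleukin receptor subunits that it holds (adjusted p = 2.15e-16; adjusted p = 0.00119 with an estimated correlation), with Ifnar1 at 0.62 ± 0.14, Ifnar2 at 0.66 ± 0.19, Ifngr2 at 0.62 ± 0.16 and Il10rb at 0.59 ± 0.15. Gene by gene, edgeR called 0 of the 109 over all genes tested, while 42 had an unadjusted p under 0.05, 25 passed when adjusted over the list alone, DESeq2 called 11 and limma-trend on RPKM 0. With the length slope as a covariate, 36 were called, among them App (0.64 ± 0.09, edgeR adjusted p = 0.000761, with a range of 0.000761 to 1 over its alternatives), Jam2 (0.81 ± 0.10), Rcan1 (0.60 ± 0.08), a calcineurin inhibitor, Synj1 (0.69 ± 0.11), a synaptic phosphatase, and Sod1 (0.45 ± 0.07).

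**Figure D3:**
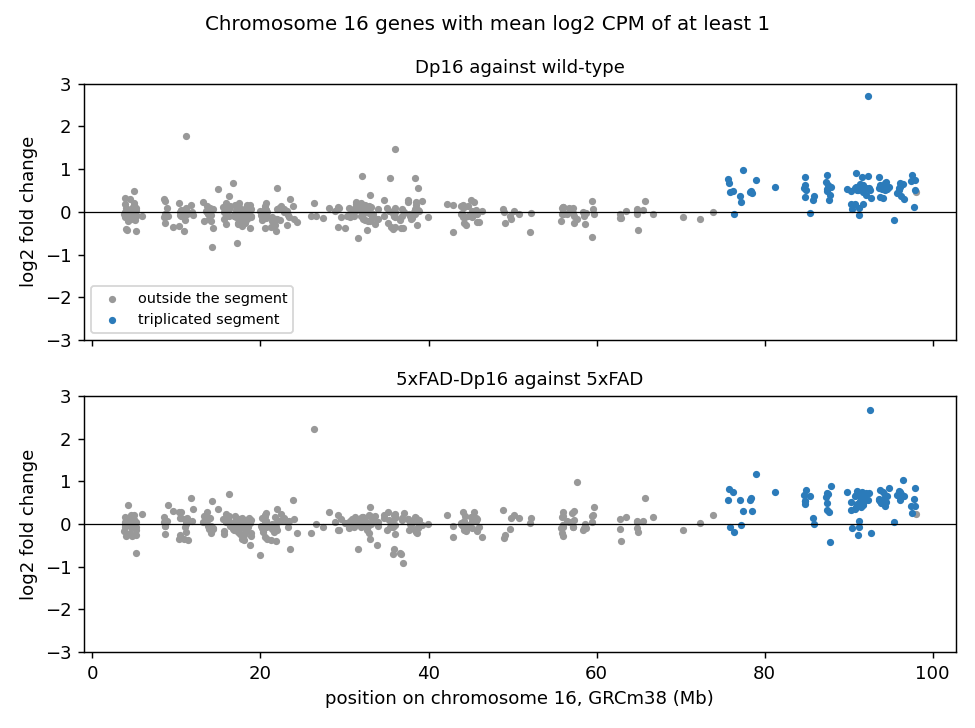
Log2 fold change (y axis) of chromosome 16 genes by position in Mb on GRCm38 (x axis), for Dp16 against wild-type and 5xFAD-Dp16 against 5xFAD; each point is a gene with a mean log2 CPM of at least 1, and the triplicated segment is in blue. The medians of all tested segment genes were 0.55 and 0.57, against −0.03 and 0.02 for the rest of the chromosome.

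Outside the segment, edgeR called a single gene in Dp16 against wild-type, and DESeq2 called 3. It was nonagouti (symbol a, ENSMUSG00000027596, chromosome 2, 154791402 to 155051012), a pigment signalling gene, named after its values were seen. Its counts were 49 to 77 in the 4 Dp16 libraries and 0 to 2 in the wild-type libraries, or 255 against 2 counts in total, a ratio of 110 (exact Poisson 95% interval 30.3 to 917, counting error only; edgeR adjusted p = 0.00265). Over the whole comparison 1 gene rose and 0 fell, with 386 at an unadjusted p under 0.05; limma-trend called 1. DESeq2 called 14, the fit without the low-count filter 20 (19 outside the segment) and the fit with the length slope 44 (42 higher and 2 lower, 8 outside the segment). Leaving out wild-type replicate 3 gave 2. Voom weights gave 4491, with the highest weights on wild-type replicate 1 (length slope 0.281) and Dp16 replicate 4 (length slope −0.181). Fitting only these 8 libraries gave 0 calls: the nonagouti log2 fold change was 6.55 ± 0.62 before and 6.55 ± 0.69 in that fit, while its degrees of freedom went from 12.3 to 8.54 and its edgeR adjusted p to 0.136 (range over its alternatives 1.07e-16 to 0.136).

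No cell-type, immune or organelle list passed in Dp16 against wild-type once the correlation was estimated. The 23 oligodendrocyte and myelin genes were all below 0 (median −0.35), with Enpp6 at −0.76 ± 0.23 and Mbp at −0.35 ± 0.18, and passed at the preset correlation (adjusted p = 8.2e-09; adjusted p = 0.285 with an estimated correlation). Reactive astrocyte genes had a median of 0.24 (adjusted p = 0.000685; adjusted p = 0.421 with an estimated correlation), and interferon-stimulated genes 0.19 (adjusted p = 0.0213; adjusted p = 0.861 with an estimated correlation). Choroid plexus and ependyma markers, a neighbouring tissue, had a median of 0.91 with an adjusted p of 0.421 at the estimated correlation. Plaque-associated microglia genes had a median of 0.05 (camera adjusted p = 0.0674). At the preset correlation 10 lists passed, 6 without Dp16 replicate 3 and 16 without Dp16 replicate 1, and arbitrary splits of the same libraries passed up to 20.

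Several genes of plaque-associated microglia were among those that rose most in 5xFAD cortex. Cst7, a cystatin, went from 0.753 ± 0.576 to 131 ± 45.5 CPM (log2 fold change 7.46 ± 0.63, edgeR adjusted p = 5.01e-05). Itgax, encoding CD11c, rose by 7.01 ± 0.65, the lectin receptor Clec7a by 6.14 ± 0.64 and the chemokine Ccl3 by 5.62 ± 0.65 on the log2 scale. Hcar2 rose from 3 counts in the wild-type libraries to 416 in 5xFAD, a ratio of 118 (exact Poisson 95% interval 40.2 to 576, counting error only). Altogether 264 genes rose and 2 fell relative to wild-type, against 700 and 226 with the length slope as a covariate. The 2 were Mme, encoding the amyloid-degrading peptidase neprilysin (−0.85 ± 0.20, adjusted p = 0.0424), and Emb (−0.59 ± 0.14, adjusted p = 0.044).

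The microglial response was broad. Of 35 tested plaque-associated genes 23 rose over all genes tested and 31 when adjusted over the list alone (median 2.38; camera adjusted p = 5.34e-05 with an estimated correlation). Pan-myeloid genes rose in 12 of 16, with C1qa at 1.80 ± 0.17 and Ctss at 1.92 ± 0.19 (16 over the list alone; adjusted p = 0.000135 with an estimated correlation). Homeostatic microglia genes were also higher (7 of 23 called, 15 over the list alone, median 0.88; adjusted p = 0.000958 with an estimated correlation), with Fcrls at 1.71 ± 0.22 and Cx3cr1 at 1.23 ± 0.23. Lysosomal genes rose in 14 of 43 (18 over the list alone), including Cd68 (2.60 ± 0.26) and Ctsd (1.83 ± 0.21), with an adjusted p of 0.000754 at the estimated correlation.

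Antigen presentation, complement and interferon genes rose with them. MHC class II genes rose in 6 of 7 (7 over the list alone; median 2.90; adjusted p = 0.00103 with an estimated correlation), led by the invariant chain Cd74 at 4.18 ± 0.54 and H2-Aa at 4.10 ± 0.61. MHC class I genes rose in 6 of 16 (13 over the list alone), with B2m at 1.52 ± 0.15 (list adjusted p = 0.00118 with an estimated correlation). Complement genes rose in 9 of 18 (10 over the list alone; adjusted p = 7.83e-05 with an estimated correlation) and interferon-stimulated genes in 18 of 35 (32 over the list alone; adjusted p = 0.00187 with an estimated correlation), with Irf7 at 2.04 ± 0.30 and Bst2 at 2.09 ± 0.34. Genes of the list of NF-kB and inflammatory cytokines rose in 3 of 27 (10 over the list alone, camera adjusted p = 0.00015 with an estimated correlation). They were the receptor gene Tlr2 (2.77 ± 0.37) and the chemokine genes Cxcl10 (3.30 ± 0.51) and Cxcl16 (1.94 ± 0.34).

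Among macroglia, reactive astrocyte genes rose in 10 of 29 in 5xFAD (14 over the list alone; adjusted p = 0.000285 with an estimated correlation), with Gfap at 3.04 ± 0.26, Serpina3n at 2.73 ± 0.29 and C4b at 3.10 ± 0.41. Disease-associated oligodendrocyte genes rose in 5 of 14 (5 over the list alone; adjusted p = 0.000779 with an estimated correlation), of which B2m, Serpina3n, C4b and H2-D1 also stand in other lists. General astrocyte markers had a median of 0.30, with Aqp4 called (0.70 ± 0.17, edgeR adjusted p = 0.0459), and the list did not hold (adjusted p = 0.12 with an estimated correlation). Myelin genes had a median of 0.10 (camera adjusted p = 0.118).

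Inhibitory neuron genes were lower in 5xFAD than in wild-type as a list: 24 of 25 were below 0, with a median of −0.35 (camera adjusted p = 5.76e-06; adjusted p = 0.00171 with an estimated correlation). The edgeR fit without the length slope and with its low-count filter called 0 members singly, over all genes or over the list alone. The gene values that follow are of that fit. Sst stood at −0.64 ± 0.22 (edgeR adjusted p = 0.339), Gad1 at −0.35 ± 0.14 (adjusted p = 0.527) and Vip at −0.67 ± 0.28 (adjusted p = 0.579). Striatal markers moved the same way, with a median of −0.37 (camera adjusted p = 0.0014; adjusted p = 0.434 with an estimated correlation). Oxidative phosphorylation genes (median −0.30) and proteasome genes (median −0.29) passed at the preset correlation and had adjusted p of 0.721 and 0.692 with an estimated correlation.

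The 266 calls of 5xFAD against wild-type became 167 without wild-type replicate 1, 169 without wild-type replicate 2, 424 with DESeq2, 426 without the low-count filter, 926 with the length slope as a covariate, 1200 with voom weights and 115 when only these 8 libraries were fitted. Of the 24 lists past the threshold at the preset correlation 12 held with an estimated one, and other splits of the 8 libraries gave up to 24 at the preset correlation but at most 1 with an estimated one.

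Mice with both genotypes showed the microglial and astrocytic changes together with the segment dosage. Relative to wild-type, 87 genes rose and 1 fell in 5xFAD-Dp16, with Cst7 at 6.40 ± 0.61, Itgax at 5.85 ± 0.65, Clec7a at 5.26 ± 0.62 and Thy1 at 1.30 ± 0.14 (edgeR adjusted p = 0.000651). The gene that fell was Myoc, encoding myocilin (−1.35 ± 0.26, adjusted p = 0.0261). Plaque-associated microglia genes rose in 12 of 35 (25 over the list alone; median 1.76; adjusted p = 7.58e-05 with an estimated correlation), pan-myeloid genes in 6 of 16 (15 over the list alone), complement genes in 7 of 18 (9 over the list alone) and reactive astrocyte genes in 6 of 29 (11 over the list alone), with Gfap at 2.39 ± 0.25 and Serpina3n at 2.56 ± 0.29. In the segment 7 of 109 genes were called and 34 over the list alone, among them Jam2 (0.84 ± 0.13), Ifnar1 (0.76 ± 0.14) and Ifnar2 (1.05 ± 0.19). Samsn1, another of the 7 (2.25 ± 0.36), rose by 2.33 ± 0.36 in 5xFAD without Dp16 (edgeR adjusted p = 0.00206) and stood at −0.08 in 5xFAD-Dp16 against 5xFAD, so its rise came with the transgenes. Of 20 lists past the threshold, 13 held with an estimated correlation. The 88 calls became 40 and 43 without wild-type replicates 1 and 2, 49 and 46 without 5xFAD-Dp16 replicates 1 and 4, and 9 when only these 8 libraries were fitted. They became 214 with DESeq2, 258 without the low-count filter, 358 with the length slope, 510 with voom weights and 175 without the 3 libraries of lowest slope.

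The amyloid transgenes also raised microglial and complement genes and Gfap on the Dp16 background. In 5xFAD-Dp16 against Dp16, 68 genes rose and 0 fell, with 688 at an unadjusted p under 0.05; DESeq2 called 165 and limma-trend 56. Cst7 rose by 7.09 ± 0.63, Itgax by 4.70 ± 0.57, Clec7a by 4.10 ± 0.57, the oxidase subunit Cybb by 3.21 ± 0.61 and Ly9 by 3.17 ± 0.56 on the log2 scale. Gfap rose by 2.00 ± 0.25 (edgeR adjusted p = 0.00174) and Samsn1, a segment gene, by 1.78 ± 0.35 (adjusted p = 0.0353). Plaque-associated microglia genes rose in 12 of 35 (27 over the list alone; median 1.36; adjusted p = 0.000336 with an estimated correlation), pan-myeloid genes in 6 of 16 (16 over the list alone; adjusted p = 0.000336) and complement genes in 6 of 18 (9 over the list alone; adjusted p = 0.000336). Of 7 MHC class II genes the edgeR fit without the length slope and with its low-count filter called 0 over all genes tested and 5 over the list alone. In that fit Cd74 stood at 2.41 ± 0.50 (adjusted p = 0.0565). The MHC class II list had a camera adjusted p of 0.03 with an estimated correlation. Inhibitory neuron genes had a median of −0.13 (camera adjusted p = 0.0397; adjusted p = 0.118 with an estimated correlation). The 68 calls became 22, 33 and 42 without Dp16 replicates 2, 3 and 4, 31 and 36 without 5xFAD-Dp16 replicates 1 and 4, 127 without wild-type replicate 3, 236 without the low-count filter, 212 with the length slope, 221 with voom weights and 44 when only these 8 libraries were fitted.

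Adding Dp16 to 5xFAD raised the segment genes again. In 5xFAD-Dp16 against 5xFAD, 97 of 109 segment genes were above 0, with a median of 0.57 (interquartile range 0.38 to 0.74), or 1.49-fold, against 0.02 for the rest of chromosome 16 (camera adjusted p = 2.09e-51; adjusted p = 6.82e-09 with an estimated correlation). App stood at 0.79 ± 0.24 (edgeR adjusted p = 1), Rcan1 at 0.73 ± 0.14 (adjusted p = 0.263), Brwd1 at 0.66 ± 0.12 (adjusted p = 0.263) and Ttc3 at 0.68 ± 0.13 (adjusted p = 0.263). The 4 receptor subunits passed as a list (adjusted p = 0.00544 with an estimated correlation), with Ifnar1 at 0.64 ± 0.14 and Ifngr2 at 0.70 ± 0.16. Singly, edgeR called 0 segment genes, with 51 at an unadjusted p under 0.05 and 45 past the threshold over the list alone; DESeq2 called 11 and limma-trend on RPKM 0. With the length slope 47 were called, App among them at 0.78 ± 0.09 (adjusted p = 4.22e-05, with a range of 4.22e-05 to 1 over its alternatives) and Pcp4, a calmodulin regulator, at 1.09 ± 0.09, and 34 segment genes were called in both Dp16 comparisons.

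Myeloid genes were lower in 5xFAD-Dp16 than in 5xFAD as lists. Plaque-associated microglia genes had a median of −0.58, with 33 of 35 below 0 (camera adjusted p = 2.36e-17; adjusted p = 0.028 with an estimated correlation). Homeostatic microglia genes had a median of −0.42 and pan-myeloid genes of −0.53 (adjusted p = 0.0295 for each with an estimated correlation), and MHC class II genes of −1.37 (adjusted p = 0.04 with an estimated correlation). The score of the plaque-associated list was 1.32 ± 0.287 in 5xFAD and 0.74 ± 0.521 in 5xFAD-Dp16, against −1.11 ± 0.248 in wild-type (SD, n = 4), so it remained far above wild-type. No member was called singly over all genes in the edgeR fit without the length slope and with its low-count filter: Igf1 stood at −0.85 ± 0.19 (adjusted p = 0.542), Itgax at −1.16 ± 0.44, Cd68 at −0.67 ± 0.25 and H2-Aa at −1.76 ± 0.56 (adjusted p = 1 for each). Among named members H2-Aa, H2-Ab1, Cd74 and Itgax were called lower without the filter, Igf1 and C1qa with the length slope, and Igf1 with DESeq2 and voom weights, and the H2-Aa value was −1.13 without 5xFAD replicate 4. Adjusted over the list alone, 5 of 7 MHC class II genes, 2 of 18 complement genes and 1 of 35 plaque-associated genes were lower. With the length slope and an estimated correlation the adjusted p were 0.113, 0.0897, 0.113 and 0.195 for the plaque-associated, homeostatic, pan-myeloid and MHC class II lists.

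**Figure D4:**
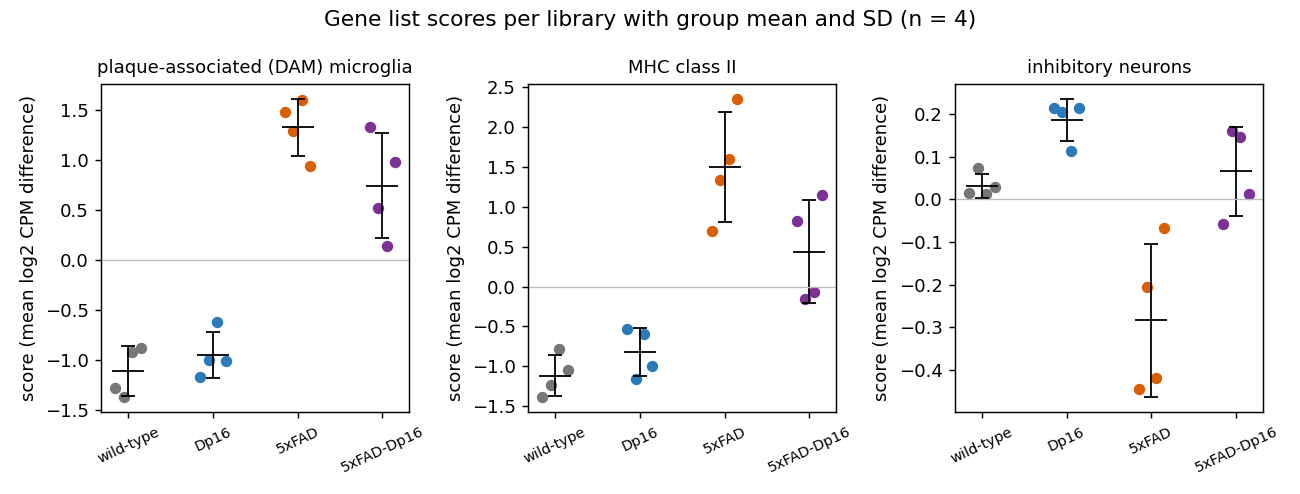
Mean log2 CPM difference over the members of 3 gene lists (y axis) by genotype (x axis), each relative to the gene's mean over all libraries; points are libraries, lines the group mean and bars the SD (n = 4). Plaque-associated microglia scores averaged 1.32 in 5xFAD and 0.74 in 5xFAD-Dp16, and inhibitory neuron scores −0.28 and 0.07.

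Inhibitory neuron genes were higher in 5xFAD-Dp16 than in 5xFAD. Their median was 0.43, with 22 of 25 above 0 and 2 called over the list alone (camera adjusted p = 4.33e-11; adjusted p = 0.000464 with an estimated correlation, and 0.00613 as the adjusted p when the length slope was added). The neuropeptide genes Cort (0.88 ± 0.24, edgeR adjusted p = 0.977), Tac2 (0.68 ± 0.20) and Npy (0.46 ± 0.16) and the GABA-synthesis gene Gad2 (0.50 ± 0.17; adjusted p = 1 for these 3) had the smallest p. Striatal markers were higher in the same comparison, with a median of 0.44 and 13 of 13 above 0 (camera adjusted p = 8.88e-10; adjusted p = 0.105 with an estimated correlation), and Penk at 0.75 ± 0.29. Tac1 stands in both lists, and whether a different dissection moved them was not tested. The fall of the inhibitory list in 5xFAD against wild-type used the same 5xFAD libraries, so that fall and this rise are not independent. Astrocyte markers had a median of −0.30 (camera adjusted p = 1.01e-08; adjusted p = 0.0574 with an estimated correlation) and myelin genes of −0.23 (camera adjusted p = 4.98e-05; adjusted p = 0.233 with an estimated correlation).

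Outside the segment the only edgeR call of 5xFAD-Dp16 against 5xFAD was nonagouti, with 45 to 83 counts in the 5xFAD-Dp16 libraries and 0 counts in the 4 5xFAD libraries. Taking 3 counts per library as the floor, it was at least 19-fold higher (edgeR adjusted p = 0.00107). In all, 1 gene rose and 0 fell, with 631 at an unadjusted p under 0.05; DESeq2 called 22 and limma-trend 1. Fitting only these 8 libraries gave 20 calls (12 in the segment, 8 outside), leaving out wild-type replicate 3 gave 8 (7 in the segment), and no low-count filter and voom weights gave 42 each (38 and 20 outside). The fit with the length slope called 122, of which 25 outside the segment were higher and 50 lower. Among these, chosen by the named-gene rule applied to that fit, Myoc (−1.38 ± 0.23), Tbxas1 (−1.28 ± 0.24), Cbs (−0.99 ± 0.13), Igf1 (−0.84 ± 0.17) and C1qa (−0.55 ± 0.12) fell, and Selenov (2.27 ± 0.32), Cort (0.90 ± 0.17), Sst (0.59 ± 0.12) and Gad2 (0.49 ± 0.11) rose.

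Whether single genes differed in the transgene effect with Dp16 depended on the method and on the low-count filter. With the filter edgeR called 0 genes for the interaction, with 239 at an unadjusted p under 0.05, and limma-trend called 0. DESeq2 called 3, of which 2 had 4 counts each over all libraries and the other was Gm49041. Without the filter edgeR called 25, among them H2-Aa, H2-Ab1, Cd74, Gm42418 and Ttr. Gm42418 took 3.87% of the counts in Dp16 replicate 3 and 0.11 to 0.22% in the other Dp16 libraries. Ttr ranged from 5.21 to 1250 CPM within the Dp16 group, so calls of that fit can rest on few libraries. In the filtered edgeR fit the smallest p belonged to Gm49041 (−3.85 ± 0.75) and Rab7b, a late endosomal GTPase (−1.86 ± 0.37; adjusted p = 1 for each over all genes). As lists, plaque-associated microglia genes (median −0.57) and MHC class II genes (median −1.77) had a smaller transgene effect with Dp16 (adjusted p = 0.0472 for each with an estimated correlation), although fry passed 0 lists and with the length slope 0 held at an estimated correlation. At the preset correlation 19 lists passed, and 12 without 5xFAD-Dp16 replicate 3. The choroid plexus list had a median of 0.74 while its test pointed down.

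In the edgeR fit most genes called for the transgenes had the same sign on both backgrounds. Of the 266 genes called in 5xFAD against wild-type, 265 had the same sign in 5xFAD-Dp16 against Dp16, 65 were called in both and 250 had a smaller log2 fold change on the Dp16 background. Of the 68 called on the Dp16 background all 68 had the same sign on the wild-type background, and 14 were smaller there. Genes picked for a large effect in a comparison tend to be smaller in another. The correlation over all genes, which are not independent replicates, was r = 0.517 (rho = 0.406). It fell to 0.287 without wild-type replicate 3 and 0.285 with voom weights. With DESeq2 it was 0.114, but over every gene with any count, near-empty genes included, so the values are not over the same genes. With voom weights 64.2% of the genes called in 5xFAD against wild-type had the same sign. For the Dp16 effect the correlation was 0.453 (rho = 0.337) over the 109 segment genes and 0.173 (rho = 0.188) over 17446 genes outside the segment. With DESeq2 the latter was 0.0287, again with near-empty genes included.

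Whether sex separated the effects of either genotype gene by gene also depended on such choices. With the low-count filter edgeR called 0 genes for the difference of the 5xFAD effect between females and males, with 803 at an unadjusted p under 0.05, and 0 for the Dp16 effect, with 268; DESeq2 and limma-trend called 0 in each, and edgeR without the filter called 63 and 15. Among the genes of smallest p were the heat shock gene Hspb1 in the 5xFAD contrast (1.52 ± 0.29, edgeR adjusted p = 0.634) and Tmem252 in the Dp16 contrast (−2.15 ± 0.49, adjusted p = 1). Each cell of genotype and sex held 2 libraries, and without wild-type replicate 1, which leaves 1 female wild-type library assumed to vary like the other groups, 3352 genes were called for the 5xFAD effect by sex.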

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

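The tests of Hprt, of the match with Dp16 status, of 5xFAD-Dp16 replicate 3, of Thy1 and of the length slope on the microglial list were chosen only after the result was seen; the test of the chromosome 2 neighbours was set before.

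Of 256 groups of 4 values examined for a library far from the other 3, 10 were found, where chance would give about 12.8, or 1 in 20. Dp16 replicate 3 stood apart most often: Gm42418, which overlaps ribosomal RNA sequence, took 3.87% of its counts against 0.11 to 0.22% in the other Dp16 libraries, Gfap stood at 550 CPM (205 to 231 in the others), Clec7a at 6.1 (0.788 to 1.69), Apoe at 2180 (2850 to 2880) and the inhibitory neuron score at 0.112 (0.204 to 0.215). Gfap stood at 290 CPM in wild-type replicate 3 (197 to 204 in the others). Ttr, a choroid plexus transcript, stood at 615 CPM in 5xFAD replicate 4 (15 to 30.5). The proteasome score of 5xFAD-Dp16 replicate 2 was 0.201 (−0.187 to −0.174).

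Nonagouti (ENSMUSG00000027596) stood apart in wild-type replicate 4, at 0.094 CPM against 0, and in 5xFAD-Dp16 replicate 2, at 3.71 CPM against 2.2 to 2.31. Its presence at 3 or more counts matched Dp16 status in 16 of 16 libraries, but that restates the finding, and with litters unknown a chromosome 2 allele fixed in the Dp16 stock stays open. Among the 80 other genes tested within 2 Mb, 0 had an unadjusted p under 0.05 with the same sign in both Dp16 comparisons, which speaks against a linked interval of another strain, although an interval altering only this gene stays open. An agouti coat-colour cassette carried with the engineered chromosome would fit the counts. Such vectors may also carry Hprt sequence, and the smaller Hprt log2 fold change of both Dp16 comparisons with the length slope was −0.02 ± 0.12 (5xFAD-Dp16 against 5xFAD 0.24 ± 0.12), which cannot tell.

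The effect of the amyloid transgenes differed with Dp16 in 19 lists at camera's preset correlation, of which 2 held with an estimated one. Lower with Dp16 were the medians of plaque-associated microglia (−0.566), homeostatic microglia (−0.281), pan-myeloid (−0.454), interferon-stimulated (−0.503), complement (−0.427), MHC class I (−0.336), MHC class II (−1.773), lysosomal (−0.118), reactive astrocyte (−0.607), astrocyte marker (−0.203), disease-associated oligodendrocyte (−0.127) and NF-kB and inflammatory cytokine genes (−0.176). Higher were deep-layer neurons (0.246), inhibitory neurons (0.254), synaptic vesicle (0.213), postsynaptic density (0.231), striatal (0.628) and heat shock genes (0.181). Choroid plexus genes had a median of 0.735 and a mean of 0.371, but the test pointed down.

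Plaque-associated microglia genes were lower in 5xFAD-Dp16 than in 5xFAD, and 3 explanations were tried. Without 5xFAD-Dp16 replicate 3 the median was −0.426 (interquartile range −0.69 to −0.22), so that library alone did not carry it. With the length slope it went from −0.584 (−0.86 to −0.36) to −0.586 (−0.84 to −0.36), so the slope did not make the difference, but the call ended: the correlation camera estimated between the genes rose from 0.183 to 0.339, and the adjusted p with it from 0.028 to 0.113. Thy1, read as a stand-in for the transgene's promoter activity, had a log2 fold change of 0.24 ± 0.14, which gave no sign of weaker promoter activity. Its counts include the mouse gene itself, and the transgene RNA was not measured, so lower transgene expression was not excluded. A smaller myeloid response, fewer myeloid cells and a different dissection, as the striatal markers moved too, stay open.

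The 5xFAD effect differed between females and males in 17 lists at the preset correlation and in 0 with an estimated one. Female minus male medians were 0.394 for plaque-associated microglia, 0.451 homeostatic microglia, 0.587 pan-myeloid, 0.528 complement, 0.268 lysosome, 0.473 reactive astrocytes, 0.323 astrocyte markers, 0.581 oligodendrocyte precursors, 0.814 endothelial cells, 0.95 mural cells, 1.769 choroid plexus, 0.394 upper-layer neurons, 0.381 postsynaptic density, 0.409 striatum and 0.229 NF-kB and inflammatory cytokines. Oxidative phosphorylation (−0.695) and proteasome genes (−0.655) ran the other way. No list test by sex used the length slope as a covariate, so its part was not tested. Slopes ran from 0.019 to 0.156 in females with the transgenes and from −0.439 to 0.281 in females without them. In males they ran from −0.129 to 0.157 and from −0.181 to 0.158.

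The Dp16 effect differed between the sexes in 12 lists at the preset correlation and in 0 with an estimated one. Female minus male medians were 0.15 for plaque-associated microglia, 0.121 pan-myeloid, 0.241 interferon-stimulated genes, 0.481 MHC class I, 1.239 MHC class II, 0.332 reactive astrocytes, 0.967 choroid plexus and 0.452 hippocampus. Negative medians were those of astrocyte markers (−0.199), mitochondrially encoded genes (−0.175), the unfolded protein response (−0.158) and heat shock genes (−0.279).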

How the results depend on the processing

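The tests with the length slope, without the 3 libraries of lowest slope and with voom quality weights were chosen only after the result was seen. There were 4 libraries per group, 1 age and 1 brain region. The p-values set group differences against the spread between samples, which the main fit estimated over all 16 libraries. Of 568 named-gene results 111 were called, of which 57 lost the call in some setting, 54 kept it in all and 0 reversed. Replicate numbers did not pair samples (r above 0.1 in 9 of 24 pairs, −0.354 to 0.514; 7 of 16 libraries correlated best with their own number), and as a block they left 0 calls in Dp16 against wild-type, 0 of them outside the segment: nonagouti went from 6.55 ± 0.62 to 6.58 ± 0.70 with degrees of freedom from 12.3 to 9.26 (edgeR adjusted p = 0.0873, range over its alternatives 1.07e-16 to 0.136). Where a setting moved a count, the cause was not tested.

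DESeq2 called 14 genes in Dp16 against wild-type (11 in the segment, 3 outside), 424 in 5xFAD against wild-type, 214 in 5xFAD-Dp16 against wild-type, 22 in 5xFAD-Dp16 against 5xFAD (11 in the segment, 11 outside), 165 in 5xFAD-Dp16 against Dp16 and 3 for the interaction. Its correlations of effects across backgrounds were r = 0.114 for 5xFAD and 0.0287 for Dp16 outside the segment. They cover every gene with any count, so they are not over the genes of the edgeR fit. In the same order of comparisons, no low-count filter gave 20 (1 in the segment, 19 outside), 426, 258, 42 (4 and 38), 236 and 25, with 63 and 15 for the 5xFAD and Dp16 effects by sex. Only the 2 groups compared gave 0, 115, 9, 20 and 44. For 5xFAD-Dp16 against Dp16 limma-trend gave 41 with RPKM + 1 and 41 without a low-value filter. The interaction restricted to the 269 genes called for 5xFAD on either background gave 2; these were chosen by the transgene effect in the same libraries, which can bias it.

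The length slope gave 44 (36 in the segment, 8 outside), 926, 358, 122 (47 and 75) and 212, with 95.6% of 5xFAD genes of the same sign on both backgrounds. Without the 3 libraries of lowest slope 5xFAD-Dp16 against wild-type gave 175 and against 5xFAD 15 (10 and 5). Voom weights gave 4491 (55 and 4436), 1200, 510, 42 (22 and 20) and 221. Their segment median was 0.64 in Dp16 against wild-type, with 64.2% of 5xFAD genes of the same sign and r = 0.285. They weighted wild-type replicate 3 by 0.0852, wild-type replicate 1 (length slope 0.281) by 2.60 and Dp16 replicate 4 (length slope −0.181) by 2.61. The 4491 calls thus compare groups weighted toward libraries of opposite slope, and whether they follow the slope was not tested.

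Lists past the threshold with an estimated correlation were 2, 12, 13, 7, 11 and 2 for the interaction. With fry they were 2 for Dp16 against wild-type, 14 for 5xFAD against wild-type, 6 for 5xFAD-Dp16 against 5xFAD and 0 for the interaction.

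With each library of the groups compared left out in turn (all 16 for the interaction, by sex and across backgrounds), calls ran from 1 to 2 (Dp16 against wild-type), 167 to 290 (5xFAD against wild-type), 40 to 106 (5xFAD-Dp16 against wild-type), 1 to 1 (against 5xFAD), 22 to 76 (against Dp16), 0 to 0 (interaction), 0 to 3352 (5xFAD by sex) and 0 to 1 (Dp16 by sex). Lists ran from 6 to 16, 21 to 23, 18 to 22, 21 to 26, 15 to 20 and 12 to 23. Segment calls were 0 to 1 and 0 to 0, calls outside it 1 to 1 in both, and segment medians 0.50 to 0.60 and 0.52 to 0.61. Over all 16 libraries, 5xFAD-Dp16 against 5xFAD ran from 1 to 8 calls (0 to 7 in the segment, 1 to 1 outside) and against Dp16 from 22 to 127, each highest without wild-type replicate 3. Across backgrounds r was 0.287 to 0.512 for 5xFAD, with 97.98 to 100% of the same sign, and 0.0788 to 0.1997 for Dp16 outside the segment.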

Other observations

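The tests of the segment median with the length slope, of wild-type replicate 3 and of nonagouti over the splits were chosen only after the result was seen; those with permuted slopes and with other splits of the libraries were set before.

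Choroid plexus RNA varied within every group. Ttr, which the choroid plexus makes in large amounts, ranged from 5.21 to 1250 CPM in Dp16 and from 6.49 to 2180 CPM in 5xFAD-Dp16, and the score of the choroid plexus list was 0.463 ± 1.256 and 0.338 ± 1.835 in these groups (SD, n = 4). Apoe stood at 3110 ± 154 CPM in wild-type, 2690 ± 340 in Dp16, 5020 ± 620 in 5xFAD and 3910 ± 851 in 5xFAD-Dp16.

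In Dp16 against wild-type edgeR called 0 segment genes without the length slope and 36 with it, while without it DESeq2 called 11 and voom weights 55, the latter beside 4436 genes outside the segment. Of 100 slope vectors, the real one and permuted ones, only 1 called as many segment genes in Dp16 against wild-type: the real one called 36 and the highest other 0. The slope did not create the rise, since the segment median with the covariate was 0.569. Wild-type replicate 3 alone did not account for most of these calls: without it 1 segment gene was called in Dp16 against wild-type, and 7 in 5xFAD-Dp16 against 5xFAD, which keeps all its libraries and had 47 with the slope. Differences in length-dependent recovery between libraries stay open as the reason, while their source, such as RNA quality, was not measured here.

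Other splits of the same libraries into groups of 4 show which counts chance can give. For Dp16 against wild-type, 3 of 35 splits called at least the real 1 gene (highest other 7387) and 3 of 35 the real 1 gene outside the segment (highest other 7342), and 25 of 35 passed at least the real 10 lists at the preset correlation (highest other 20) and 2 of 35 the real 2 lists with an estimated one (highest other 2). Chance could not be excluded for any of these 4 counts. Neither of the other 2 splits with calls outside the segment called nonagouti itself, whose log2 fold change was 6.55 in the real split and at most 2.29 in another. Nonagouti was picked because its counts separate the real groups, so this restates the finding and says nothing on chance. Only the real split, 1 of 35, reached the segment median (real 0.546, highest other 0.457) and the calls with the length slope (real 44, highest other 4). Of these 44 calls 36 lay in the segment. A share of 1 of 35 is the smallest that these splits can give. It was not adjusted over the measures, so by itself it does not exclude chance. The split with 7387 calls differed in mean length slope by 0.347, against 0.058 for the real groups, so it follows that structure of the samples.

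For 5xFAD against wild-type, 2 of 35 splits called at least the real 266 genes (highest other 4438), and that split also followed the length slope, with a difference of 0.338 against 0.021. The real 24 lists at the preset correlation were reached by 3 of 35 (highest other 24), so chance could not be excluded for either. Only the real split, 1 of 35, reached the real 12 lists with an estimated correlation (highest other 1) and the real 926 genes with the length slope (highest other 9).

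In 5xFAD-Dp16 against wild-type only the real split, 1 of 35, reached 88 genes (highest other 0), 13 lists with an estimated correlation (highest other 7) and 358 genes with the length slope (highest other 43), whereas 13 of 35 reached 20 lists at the preset correlation (highest other 24). In 5xFAD-Dp16 against Dp16 the real split alone, 1 of 35, reached 68 genes (highest other 0), 11 lists with an estimated correlation (highest other 1) and 212 genes with the length slope (highest other 6), whereas 16 of 35 reached 17 lists at the preset correlation (highest other 24). In 5xFAD-Dp16 against 5xFAD the real split was alone, 1 of 35, in every measure: 1 gene and 1 outside the segment (highest other 0 each), 25 lists (highest other 24), 7 lists with an estimated correlation (highest other 6), 122 genes with the length slope (highest other 26) and a segment median of 0.574 (highest other 0.374). Both list counts include the triplicated segment and its receptor subunits, so they do not show that the myeloid or neuronal lists exceed chance. The 1 gene was nonagouti, picked by its counts, so its call says nothing on chance.

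For the interaction, 100 of 100 draws reached the real 0 genes (highest other 2350) and 100 of 100 the real 0 with the length slope (highest other 50), as any draw must reach 0, so neither informs on chance. The real 19 lists were reached by 43 of 100 (highest other 28), so chance could not be excluded. With an estimated correlation 3 of 100 reached the real 2 lists (highest other 8). These draws moved the group labels over all 16 libraries, which removes the main genotype effects too. They therefore cannot exclude chance for the interaction alone. The correlation of the 5xFAD effect across backgrounds was reached by 1 of 100 (real 0.517, highest other 0.458), and that of the Dp16 effect outside the segment by 21 of 100 (real 0.173, highest other 0.647). By sex, 100 of 100 draws reached the real 0 genes for the 5xFAD effect (highest other 1) and 100 of 100 for the Dp16 effect (highest other 6703), which again any draw must.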
